A study of Mus musculus with 62 samples.

How the data were processed

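Neocortex libraries of 62 mice in 12 groups were analysed, with 5 to 7 libraries per group. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a stranded poly(A) selection kit and sequenced on an Illumina instrument. The same protocol text names LLC cells and a time point of 3 weeks, which match neither the cells nor the weeks of these groups, so it is uncertain how far it describes these libraries. The authors deposited a single table with 47643 genes in rows and a TPM value (transcript abundance scaled to a common sum) for each library in columns. The deposited TPM columns have the same sum, and 22257 genes are at 0 in every library. The genome build is mm10, per the submitters' processing notes. The aligner, the quantification tool, the annotation and whether counting used strand are not given in the sources used here, so antisense genes such as Mettl5os are uncertain. There were 27 symbols that had been turned into dates by a spreadsheet, and none of these is named. Of the symbols 45108 matched the GENCODE vM21 annotation of GRCm38, which supplied gene types, exon lengths and coordinates.

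TPM keeps no library total, so depth was estimated from the steps of low values. For genes with an exon length, 86.1% of 205923 values between 0.5 and 10 reads were whole reads within a tolerance of 0.05. The resulting depth was 45.1 to 50.9 M reads per library. Depth was similar in all groups, so it gives no group a higher precision than another. No 2 libraries held identical values, and the highest correlation of 2 libraries was 0.9943. The lowest median chi-square per gene among 131 replicate pairs was 1.87, above sampling noise, so each library counted as a separate sample. Genes that share reads with near-identical copies are uncertain.

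Genes with a mean of at least 1 TPM were tested, which left 14494. Values were transformed to log2(TPM + 1) and fitted in a single linear model over the 12 groups with 50 residual degrees of freedom, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, with empirical Bayes moderation and a trend of variance with level. P-values were adjusted by the Benjamini-Hochberg method within each of 16 comparisons, and an adjusted p under 0.05 counted as a call. The comparisons were the 3 pairs of arms in each of 4 weeks, the change of the CAC to mock difference from 2 to 8 and from 6 to 8 weeks, and mock at 8 against 2 and against 4 weeks. Of 39 gene lists 36 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks only whether a list moves on balance one way. The lists of neutrophil markers, B lymphocyte markers and pigment cell genes had 2, 2 and 1 tested members and were not tested. With the preset correlation 9 to 23 lists passed in a comparison within a week, and with an estimated correlation 0 to 2, which by name were the cytokine list in CAC against mock at 6 weeks and against NCAC at 8 weeks, and oligodendrocyte precursor markers in CAC against mock at 6 weeks.

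Named genes followed a rule. It took the 10 risen and 10 fallen called genes with the largest fold change in each comparison, all genes where 5 or fewer passed, the 3 risen and 3 fallen with the lowest p where none passed, and up to 4 members with the lowest p of each list that passed or that concerned glucocorticoid, cytokine, interferon, astrocyte, immediate early or microglia genes. Clones, gene models and pseudogenes were left out of the ranking by fold. The groups, comparisons, lists and rule were chosen before the data were examined. The fit was tested on simulated data with 200 changed genes among 14494 for CAC against mock. At 6 weeks it recovered 42%, 80%, 100% and 96% of genes changed by 1.2, 1.5, 2 and 4 times, and 8.09% of its calls were false. At 8 weeks the shares were 50%, 86%, 100% and 96%, with 7.78% false. The simulated noise was independent between genes, so these shares do not cover errors that many genes of a library have in common.

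Alternatives chosen with the design were a pseudocount of 0.1, no filter on level, TMM scaling of the TPM values (a trimmed mean with 30% of ratios and 5% of levels trimmed), robust moderation, the replicate number as a block, lane as a term at 4 weeks, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were limma's voom on reads estimated from TPM, 6 marker scores as terms (choroid plexus, striatum, thalamus, erythroid, olfactory, and hypothalamus with pituitary), leaving out 3 libraries that stood apart in thalamus, erythroid or striatum markers, and fry. Libraries far from the median only in olfactory or hypothalamus and pituitary markers were not left out in that fit. Other splits of the samples, 100 for each comparison, were drawn at random with fixed seeds.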

Results

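Polyadenylated RNA of the neocortex was sequenced from female mice that had been injected at 2 months of age with melanoma cells that cause cachexia (CAC), with melanoma cells that do not (NCAC), or by mock injection (Con). Cachexia is a wasting of muscle and fat that accompanies some cancers. Tissue was taken 2, 4, 6 and 8 weeks after injection, which gave 12 groups and 62 libraries, with 5 libraries in each group except CAC at 8 weeks, which had 7. The titles of these 7 libraries carry the numbers 19, 21, 23, 24, 27, 28 and 30, whereas the numbers of each other group run without gaps. Whether mice were lost or left out of this group was not examined. The design text names athymic nude mice as the host, whereas the sample labels name C57BL6/J, and the strain is therefore left open here. The labels call the libraries of a group biological replicates. The steps of the deposited values gave an estimated 45.1 to 50.9 M reads per library, with a median of 48.4 M. A transcript with 2000 bases of exon and a level of 1 TPM (transcript abundance, scaled to a sum of 1000000 per library) corresponded to 28.1 reads in the median library. Fold changes are on the log2(TPM + 1) scale, which understates the changes of genes of low level, and adjusted p-values are from limma.

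Sequencing lane was not balanced over the weeks. The libraries of week 2, those of CAC at 4 weeks and 4 of the 5 libraries of NCAC at 4 weeks were run on lane 3, and all others on lane 4. Within weeks 2, 6 and 8 all libraries shared a lane. Xist, which is expressed from the inactive X chromosome of female cells, was at 181 ± 4.35 TPM (SD, n = 5) in the mock libraries of week 8 and at 151 ± 18.8 TPM (n = 7) in those of CAC. Higher thalamus, higher erythroid or lower striatum markers set 3 libraries apart by more than 3 log2 units from the median of all libraries. Mock 2 week replicate 5 had thalamus markers higher by 3.42 and hypothalamus and pituitary markers higher by 7.28. CAC 4 week replicate 1 had striatum markers lower, at -3.58, and CAC 8 week replicate 3 had erythroid markers higher by 4.27. Olfactory markers, which were not used to set libraries apart, also lay more than 3 units above their median in mock 2 week replicate 3, NCAC 2 week replicate 4, NCAC 4 week replicate 3 and CAC 8 week replicate 5, with scores of 5.43, 4.66, 4.78 and 4.51. Hypothalamus and pituitary markers did so in NCAC 4 week replicate 1, with a score of 4.32. These 5 libraries were not left out as a set.

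The comparison of CAC with mock-injected mice at 8 weeks asked how the neocortex differs late in cachexia, and 1247 of 14494 tested genes differed, 712 of them higher and 535 lower. TMM scaling gave 665 higher and 675 lower, and voom 692 and 668. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose from 0.501 ± 0.249 TPM (SD, n = 5) to 5.24 ± 3.62 TPM (n = 7), a log2 fold change of 1.92 ± 0.21 (SE, adjusted p = 1.65e-08). Lrg1, a secreted leucine-rich glycoprotein of the acute phase, rose from 2.28 ± 1.69 to 15.1 ± 6.16 TPM (log2 fold change 2.30 ± 0.27, adjusted p = 7.89e-08). The lipid droplet gene Plin4 rose by 2.94 ± 0.60 (adjusted p = 0.000946) and the secretoglobin Scgb3a1 by 2.81 ± 0.34 (adjusted p = 2e-07). Gkn3 fell by 1.89 (SE 0.30, adjusted p = 3.44e-05), Opalin, a myelin membrane protein of oligodendrocytes, fell by 1.22 (SE 0.21, adjusted p = 8.1e-05), and Apln, the ligand of the apelin receptor, fell by 1.10 (SE 0.16, adjusted p = 4.45e-06). In the GRCm38 build with the GENCODE vM21 annotation, the protein-coding genes Lcn2, Lrg1, Plin4 and Opalin lie on chromosome 2 from 32384633 to 32388252, on chromosome 17 from 56119678 to 56122001, on chromosome 17 from 56100591 to 56109803 and on chromosome 19 from 41061710 to 41077113.

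All 16 tested members of the glucocorticoid-responsive list rose at 8 weeks (16 adjusted over the list alone), with a median log2 fold change of 0.80. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 16.2 ± 2.22 TPM (SD, n = 5) to 48.9 ± 17.9 TPM (n = 7), a log2 fold change of 1.44 ± 0.23 (SE, adjusted p = 2.83e-05). The kinase gene Sgk1 rose by 1.39 ± 0.24, the sulfotransferase gene Sult1a1 by 1.87 ± 0.32 and Arrdc2 by 1.16 ± 0.19. Relative to other genes the list was higher by camera (adjusted p = 9.91e-19), with an adjusted p = 0.0628 with an estimated correlation. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 2.21e-05. At the preset correlation 16 lists passed, and other splits of the same libraries gave a median of 14. Of the 22 genes on the cytokine and acute inflammatory list 11 passed the filter on level and were tested. These, called cytokine genes below, include receptors and acute phase genes such as Il1r1, Osmr and Lrg1. Lcn2 had a group mean above 1 TPM only in CAC at 6 and 8 weeks, so it passed the filter through those groups. Of the 11 tested members 7 rose and 1 fell (8 and 1 adjusted over the list alone). Cebpd, a transcription factor induced in inflammation, rose by 1.46 ± 0.26, the interleukin 1 receptor gene Il1r1 by 0.78 ± 0.13, and the list had an adjusted p = 7.58e-09, or an adjusted p = 0.0628 with an estimated correlation. Among 14 reactive astrocyte genes 4 rose (4 adjusted over the list alone), namely Lcn2, Cp, Serpina3n by 0.67 ± 0.15 and Osmr by 0.55 ± 0.11. Lcn2 and Osmr are also on the cytokine list, so these list results overlap, and Gfap and Vim were not among the risen genes. The astrocyte list had an adjusted p = 0.00477, or an adjusted p = 0.409 with an estimated correlation. Serpina3n belongs to a family of near-identical copies, so its level is uncertain.

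Of 20 cholesterol synthesis genes 12 fell at 8 weeks (15 adjusted over the list alone), with a median log2 fold change of -0.29 and an adjusted p = 2.4e-15, or an adjusted p = 0.0628 with an estimated correlation. Hmgcs1, the cytosolic synthase of the mevalonate pathway, fell from 263 ± 22.1 TPM (SD, n = 5) to 173 ± 27.4 TPM (n = 7), a log2 fold change of -0.61 with an SE of 0.08 (adjusted p = 1.51e-06). Idi1 fell by 0.56, Msmo1 by 0.50 and Sc5d by 0.39. Of 15 microglia markers 8 fell (13 adjusted over the list alone), among them the purinergic receptor gene P2ry12, which fell by 0.62 (SE 0.11), and the fractalkine receptor gene Cx3cr1, which fell by 0.60 (SE 0.11). The microglia list had an adjusted p = 3.38e-12, or an adjusted p = 0.0628 with an estimated correlation. Of 14 atrophy, autophagy and FOXO target genes 5 rose (8 adjusted over the list alone), with Klf15 at 0.76 ± 0.13 and Cited2 at 0.53 ± 0.08. The list had an adjusted p = 1.61e-05, or an adjusted p = 0.0628 with an estimated correlation. Of 15 circadian clock genes 3 rose (7 adjusted over the list alone), namely Hlf by 0.42, Cry2 by 0.24 and Npas2 by 0.23. The list had an adjusted p = 0.00523, or an adjusted p = 0.409 with an estimated correlation. Cry2 had an adjusted p of 0.0579 without mock replicate 2 and of 0.0817 with only the groups compared. Npas2 had 0.0527 to 0.106 without CAC replicate 1, 2, 4, 6 or 7, 0.0577 to 0.17 without mock replicate 1, 3, 4 or 5. It had 0.0606 with TMM scaling and 0.0621 with no filter on level. Of 12 mature oligodendrocyte markers 4 fell (6 adjusted over the list alone), with Ugt8a at -0.72, and the list had an adjusted p = 0.00115, or an adjusted p = 0.409 with an estimated correlation. Astrocyte markers went both ways, with 2 of 12 higher and 4 lower (3 and 7 adjusted over the list alone). The water channel gene Aqp4 fell by 0.71 (SE 0.12) and the connexin gene Gjb6 rose by 0.57 ± 0.13.

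Ighm, the immunoglobulin mu constant region, fell in CAC mice at 8 weeks by 1.77 (SE 0.23, adjusted p = 1.26e-06), from 97.7 ± 88.4 TPM (SD, n = 5) to 23.1 ± 8.03 TPM (n = 7). Mock replicate 5 of week 8 was at 256 TPM of Ighm and the other 4 mock libraries between 54.9 and 65.7 TPM. Of 20 interferon response genes 2 fell (2 adjusted over the list alone), Gbp3 and Gbp2, and the list had an adjusted p = 9.07e-05, or an adjusted p = 0.409 with an estimated correlation. The log2 fold change was -0.99 for Gbp3, -0.91 for Gbp2, -1.07 for Lag3 and -1.09 for Tgtp2. Without mock replicate 5 of week 8 it was -0.581 (adjusted p = 0.192), -0.566 (adjusted p = 0.096), -0.671 (adjusted p = 0.19) and -0.445 (adjusted p = 0.274). Gbp3 and Lag3 also lost their calls without CAC replicate 6, with an adjusted p of 0.0547 and 0.0567. The Gbp and Tgtp genes belong to families of near-identical copies, so reads can be divided among them in ways that these values do not show. Of 18 immediate early genes 1 fell (1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.706). The count of 1247 genes was 767 without CAC 8 week replicate 1, 721 without CAC 8 week replicate 6 and 825 without mock 8 week replicate 1, and 2021 without the 3 libraries that stood apart.

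**Figure D1:**
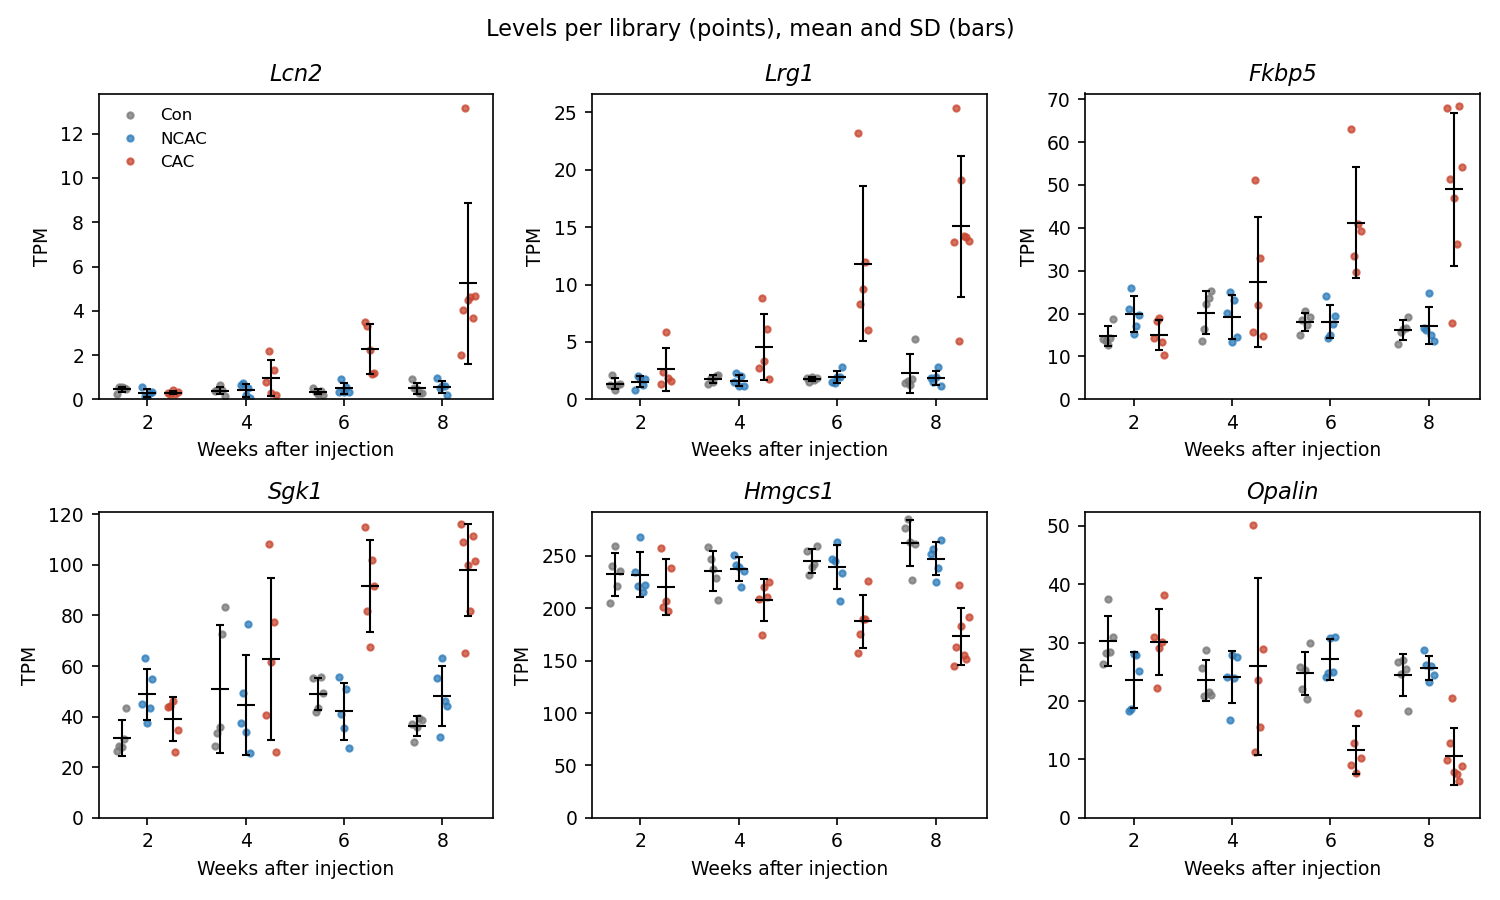
Level in TPM (vertical axis) against weeks after injection (horizontal axis) for 6 genes, with a point per library in grey (Con), blue (NCAC) and red (CAC), and black bars for the mean and SD of each group. At 8 weeks the 7 CAC libraries lay between 1.99 and 13.2 TPM for Lcn2, above the 5 mock libraries at 0.302 to 0.911 TPM.

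At 6 weeks the comparison of CAC with mock asked whether these differences were already present, and 236 genes differed, 174 higher and 62 lower. Lrg1 rose from 1.76 ± 0.189 to 11.8 ± 6.73 TPM (SD, n = 5 each), a log2 fold change of 2.08 ± 0.29 (SE, adjusted p = 1.07e-05). Scgb3a1 rose by 2.33 ± 0.37, Etnppl, an enzyme that degrades phosphoethanolamine, by 1.94 ± 0.41, and Lcn2 by 1.22 ± 0.22 (adjusted p = 0.00119). Gkn3 fell by 1.93 (SE 0.33) and Opalin by 1.08 (SE 0.22). Of 11 cytokine genes 6 rose (10 adjusted over the list alone), among them the oncostatin M receptor gene Osmr by 0.70 ± 0.12 and Il1r1 by 0.73 ± 0.14, and the list passed with a preset correlation (adjusted p = 3.47e-14) and with an estimated one (adjusted p = 0.00812). Of 16 glucocorticoid-responsive genes 5 rose (14 adjusted over the list alone), with Fkbp5 at 1.10 ± 0.25 (adjusted p = 0.089 without CAC replicate 1) and the metallothionein gene Mt1 at 0.64 ± 0.13, and the list had an adjusted p = 7.78e-14, or an adjusted p = 0.164 with an estimated correlation. Oligodendrocyte precursor markers were lower as a list (adjusted p = 4.89e-06, and 0.0431 with an estimated correlation), with 0 of 10 called by limma over all genes and 2 adjusted over the list alone. Of 20 cholesterol synthesis genes 2 fell (9 adjusted over the list alone), Hmgcs1 by 0.39 and Msmo1 by 0.32, and the list had an adjusted p = 3.95e-10, or an adjusted p = 0.183 with an estimated correlation. Cytosolic ribosomal protein genes rose as a list, with 7 of 77 called (29 adjusted over the list alone, adjusted p = 2.15e-18, or an adjusted p = 0.183 with an estimated correlation). With TMM scaling Rpl7 had an adjusted p of 0.192 and Rps14 0.074. Without CAC replicate 1 these genes had an adjusted p of 0.0999 and 0.054, and without mock replicate 3 of 0.0701 and 0.0535.

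Of the 174 genes higher at 6 weeks 140 were also higher at 8 weeks, where independent lists of these sizes would share 8.5, and of the 62 lower genes 56 were also lower, against 2.3. The test of whether the difference between CAC and mock changed from 6 to 8 weeks called 0 genes by limma, with 186 at an unadjusted p under 0.05 and 0 by voom. The genes closest to the threshold were Mettl5os at 0.71 ± 0.20 and Exoc3l4 at -0.67 (SE 0.18), each with an adjusted p of 1, and neither passed. The share of higher genes at 6 weeks was 73.7%, against 51.2% with TMM scaling and 59.8% with voom. The count of 236 was 54 without CAC 6 week replicate 1, 407 without CAC replicate 3, 131 without CAC replicate 4, 106 without mock 6 week replicate 3 and 131 without mock replicate 4. Without CAC replicate 1 the calls of Fkbp5 (adjusted p = 0.089), Sult1a1 (0.0999) and Arrdc2 (0.089) were lost.

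At 4 weeks 6 genes were higher in CAC than in mock libraries and 0 lower by limma, with 1895 at an unadjusted p under 0.05 in either direction and 2 called by voom. The count was 1 with TMM scaling, 2 with no filter on level, 1 with the 6 marker scores as terms, and 2 without the 3 libraries that stood apart. By limma it was 0 with only the groups compared, where Zfp459 had an adjusted p of 0.548. Zfp459, a zinc finger gene on chromosome 13 from 67405709 to 67421418, rose from 0.926 ± 0.133 to 3.06 ± 1.17 TPM (SD, n = 5 each), a log2 fold change of 1.03 ± 0.18 (SE, adjusted p = 0.00412). Grrp1 rose by 0.86 ± 0.17, Diablo, which encodes a mitochondrial protein that promotes apoptosis, by 0.47 ± 0.10, Zfos1 by 0.46 ± 0.10 and Ccdc9 by 0.30 ± 0.06. The sixth gene was a clone without an established symbol. Without CAC replicate 1 the adjusted p was 0.0673 for Grrp1, 0.525 for Diablo, 0.224 for Zfos1 and 0.474 for Ccdc9, and without CAC replicate 2 or 4 or mock replicate 1, 2 or 5 these 4 genes also missed the threshold, as did Ccdc9 and Zfos1 without mock replicate 3 and Grrp1, Ccdc9 and Zfos1 without mock replicate 4. Striatum markers were lower as a list, with a median log2 fold change of -0.64, 0 of 11 members called by limma and 9 adjusted over the list alone, and the list had an adjusted p = 4.61e-12, or an adjusted p = 0.305 with an estimated correlation. Adora2a was at 74.4 TPM in CAC and 103 TPM in mock libraries, and 3 of the 5 CAC libraries lay below every mock library. The striatum score, a mean of log2 levels, was 2.76 in CAC replicate 1, which stood apart, and 5.07 in CAC replicate 4, and it was 6.43 to 6.87 in the other 3 CAC libraries and 6.21 to 6.87 in mock libraries. All CAC libraries of week 4 were on lane 3 and all mock libraries on lane 4, and with lane as a term 0 genes were called by limma. That term rests on a single NCAC library of lane 4, and with it the log2 difference was 0.765 for Zfp459, 0.618 for Grrp1, 0.375 for Diablo, 0.615 for Zfos1 and 0.309 for Ccdc9. The count of 6 was 760 without CAC 4 week replicate 5, 24 without CAC replicate 3, 3 without mock 4 week replicate 3, 2 without mock replicate 4, and 1 without CAC replicate 1, 2 or 4 or mock replicate 1, 2 or 5. Lcn2, Lrg1 and Fkbp5, chosen after their 8 week values were seen, were not called but varied between CAC mice. In CAC replicates 1 to 5 Lcn2 was at 0.796, 2.17, 0.301, 1.31 and 0.201 TPM, against 0.15 to 0.631 TPM in mock libraries. Lrg1 was at 2.71, 8.84, 3.34, 6.16 and 1.80 TPM, against 1.32 to 2.14 TPM. Fkbp5 was at 15.6, 51.1, 22.1, 32.9 and 14.9 TPM, against 13.6 to 25.2 TPM.

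At 2 weeks 620 genes differed between CAC and mock libraries, 533 higher and 87 lower. Of 12 markers of excitatory cortical neurons 4 rose (6 adjusted over the list alone, adjusted p = 2.08e-05, or an adjusted p = 0.152 with an estimated correlation), among them the vesicular glutamate transporter gene Slc17a7 by 0.43 ± 0.09 (SE, n = 5 each, adjusted p = 0.00718). With the marker scores as terms the difference of Slc17a7 was 0.24 (adjusted p = 0.0944) and that of Syt1 0.29 (adjusted p = 0.0795). Of 18 synaptic genes 7 rose (12 adjusted over the list alone, adjusted p = 1.02e-06, or an adjusted p = 0.152 with an estimated correlation), such as the calcium sensor gene Syt1 by 0.34 ± 0.07. Of 10 mural cell markers 3 fell (6 adjusted over the list alone, adjusted p = 8.18e-07, or an adjusted p = 0.152 with an estimated correlation), such as the smooth muscle myosin gene Myh11, which fell by 0.67 (SE 0.16) and had an adjusted p of 0.0819 and 0.0741 without CAC replicates 1 and 5 and of 0.0501 without mock replicate 5. Of 16 endothelial markers 3 fell (3 adjusted over the list alone, adjusted p = 8.42e-07, or an adjusted p = 0.152 with an estimated correlation), such as Pecam1, which fell by 0.30 (SE 0.07) and had an adjusted p of 0.0579 and 0.052 without CAC replicates 1 and 5. Of 13 mitochondrially encoded genes 2 fell (9 adjusted over the list alone, adjusted p = 4e-08, or an adjusted p = 0.152 with an estimated correlation). These were mt-Cytb and mt-Nd2, with an adjusted p of 0.0999 and 0.106 with TMM scaling, 0.264 and 0.162 with no filter on level and 0.0841 and 0.116 with the marker scores as terms. They had 0.135 and 0.127 without CAC replicate 1, 0.123 and 0.127 without CAC replicate 5, 0.11 and 0.1 without mock replicate 1 and 0.0725 and 0.0759 without mock replicate 2. In addition mt-Nd2 had 0.0655, 0.059 and 0.0608 without CAC replicates 2 and 3 and mock replicate 5. Glucocorticoid-responsive and cytokine genes had 0 of 16 and 0 of 11 members called by limma at 2 weeks, and 0 and 0 adjusted over the list alone.

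The share of higher genes at 2 weeks was 86%, against 75.7% with TMM scaling and 56.4% with voom. With the 6 marker scores of neighbouring tissue and blood as terms 3 genes were called, with only the 10 libraries compared 0 by limma, and without the 3 libraries that stood apart 349. With the scores the median effect of the 620 genes went from 0.273 (SD 0.131) to 0.237 (SD 0.119). The median SE went from 0.072 to 0.074, and all 620 genes kept their direction. The count of 620 was 78 without CAC 2 week replicate 1, 1234 without CAC replicate 4, 79 without CAC replicate 5, 191 without mock 2 week replicate 1, 1001 without mock replicate 4 and 175 without mock replicate 5.

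The comparison of NCAC with mock asked which differences follow from a melanoma that does not cause cachexia. At 2 weeks 1262 genes differed, 851 higher and 411 lower. The excitatory neuron gene Slc17a7 rose by 0.46 ± 0.09 (SE, n = 5 each, adjusted p = 0.00348), and Syn1, a synaptic vesicle protein, by 0.28 ± 0.06 (adjusted p = 0.00399). Pecam1, an adhesion molecule of endothelium, fell by 0.42 (SE 0.07, adjusted p = 0.000697). The long noncoding RNA Meg3 fell by 0.80, with an adjusted p of 0.101 and 0.0828 without NCAC replicates 2 and 5. Of 10 mural cell markers 7 fell (8 adjusted over the list alone, adjusted p = 1.52e-07, or an adjusted p = 0.149 with an estimated correlation), and of 16 endothelial markers 6 fell (10 adjusted over the list alone, adjusted p = 1.82e-07, or an adjusted p = 0.268 with an estimated correlation). Of 15 circadian genes 5 rose (6 adjusted over the list alone), such as Dbp by 0.52 ± 0.15 and Cry1 by 0.49 ± 0.15, and the list had an adjusted p = 0.0015, or an adjusted p = 0.341 with an estimated correlation. Kl, a gene of the choroid plexus, the epithelium that secretes cerebrospinal fluid, rose by 1.35 ± 0.42. It had an adjusted p of 0.0818, 0.0988 and 0.101 without NCAC replicates 1, 2 and 5, of 0.0782, 0.0873 and 0.0594 without mock replicates 2, 3 and 4, and of 0.404 with the marker scores as terms.

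The share of higher genes in NCAC at 2 weeks was 67.4%, against 42% with voom. With the 6 marker scores as terms 111 genes were called, with only the 10 libraries compared 7, with no filter on level 780 and with TMM scaling 2038. The count of 1262 was 448 without NCAC 2 week replicate 1, 129 without NCAC replicate 2, 1900 without NCAC replicate 4, 173 without NCAC replicate 5, 664 without mock 2 week replicate 2, 692 without mock replicate 3 and 803 without mock replicate 5.

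At 4, 6 and 8 weeks limma called 0 genes between NCAC and mock libraries, with 89, 953 and 636 genes at an unadjusted p under 0.05 and 0 by voom in each week. Where no gene differs, a share of 0.05 of the 14494 tested genes would on average have such a p, so these counts are no sign of a difference by themselves. The genes with the lowest p did not pass. At 4 weeks Chd1l was at 4.37 ± 0.227 TPM in NCAC and 5.72 ± 0.494 TPM in mock libraries (SD, n = 5 each), and at 6 weeks Inafm1 was at 47.5 ± 7.03 and 37.8 ± 3.63 TPM. At 8 weeks Rnf213 was at 2.65 ± 0.742 and 4.30 ± 1.54 TPM and Pdgfb, a growth factor gene of endothelium, at 17.9 ± 1.7 and 23.7 ± 2.25 TPM. Chosen after their values in CAC were seen, Lcn2 was at 0.567 ± 0.276 TPM in NCAC libraries of week 8 (SD, n = 5) and Fkbp5 at 17.2 ± 4.36 TPM. With lane as a term 2 genes were called at 4 weeks, and with no filter on level 1 gene at 6 weeks.

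The direct comparison of CAC with NCAC sets the cachectic against the non-cachectic tumour. The injected cells differed between these arms, so cachexia cannot be told apart from any other difference between the tumours. At 8 weeks 873 genes differed, 636 higher in CAC and 237 lower. Lcn2 was higher by 1.86 ± 0.21 (SE, n = 7 and 5, adjusted p = 1.53e-08), Lrg1 by 2.41 ± 0.27 (adjusted p = 1.53e-08) and Ch25h, which encodes an enzyme that hydroxylates cholesterol, by 1.78 ± 0.21 (adjusted p = 6.4e-08). Opalin was lower, at -1.30 (SE 0.21), as were Ighm at -1.32 (SE 0.23) and Tnnc1, a troponin gene, at -0.97 (SE 0.15). Of 11 cytokine genes 8 were higher and 0 lower (9 and 1 adjusted over the list alone), and the list passed with a preset correlation (adjusted p = 4.64e-14) and with an estimated one (adjusted p = 0.00932). Of 16 glucocorticoid-responsive genes 15 were higher (16 adjusted over the list alone), such as Fkbp5 by 1.38 ± 0.23, and the list had an adjusted p = 6.1e-16, or an adjusted p = 0.0786 with an estimated correlation. Of 14 reactive astrocyte genes 7 were higher (7 adjusted over the list alone, adjusted p = 2.96e-06, or an adjusted p = 0.0974 with an estimated correlation), such as Cp, the ferroxidase ceruloplasmin, by 0.67 ± 0.12. Of 20 cholesterol synthesis genes 9 were lower (10 adjusted over the list alone, adjusted p = 6.1e-16, or an adjusted p = 0.0786 with an estimated correlation), with Hmgcs1 at -0.52 (SE 0.08). Of 12 mature oligodendrocyte markers 5 were lower (7 adjusted over the list alone, adjusted p = 1.19e-09, or an adjusted p = 0.0974 with an estimated correlation).

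The share of higher genes between CAC and NCAC at 8 weeks was 72.9%, against 47.6% with TMM scaling and 54.2% with voom. With only the 12 libraries compared 284 genes were called, and 1974 without the 3 libraries that stood apart. The count of 873 was 568 without CAC 8 week replicate 1, 1640 without CAC replicate 3, 486 without CAC replicate 6, 1446 without NCAC 8 week replicate 3, 514 without NCAC replicate 4 and 407 without NCAC replicate 5.

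At 6 weeks 1399 genes differed between CAC and NCAC, 1167 higher and 232 lower. Lrg1 was higher by 2.01 ± 0.29 (SE, n = 5 each, adjusted p = 3.44e-05), Scgb3a1 by 2.36 ± 0.37, Etnppl by 2.23 ± 0.41 and Plin4 by 2.33 ± 0.65. Gkn3 was lower, at -1.79 (SE 0.33), and Opalin at -1.21 (SE 0.22). Of 11 cytokine genes 10 were higher (10 adjusted over the list alone, adjusted p = 1.66e-08, or an adjusted p = 0.0742 with an estimated correlation). Of 16 glucocorticoid-responsive genes 10 were higher (15 adjusted over the list alone, adjusted p = 1.02e-07, or an adjusted p = 0.311 with an estimated correlation). Of 12 mature oligodendrocyte markers 6 were lower (6 adjusted over the list alone, adjusted p = 1.34e-10, or an adjusted p = 0.131 with an estimated correlation). The share of higher genes was 83.4%, against 39.2% with TMM scaling, which called 719 genes, and 56.2% with voom, which called 861. The count of 1399 was 904 with no filter on level, 304 with the 6 marker scores as terms and 628 with only the 10 libraries compared. It was 342 without CAC 6 week replicate 1, 2508 without CAC replicate 2, 558 without CAC replicate 4, 687 without CAC replicate 5, 2236 without NCAC 6 week replicate 1, 576 without NCAC replicate 2, 593 without NCAC replicate 4 and 523 without NCAC replicate 5. Plin4 had an adjusted p of 0.0707 without CAC replicate 1, of 0.0652 without NCAC replicate 2 and of 0.0707 with the marker scores as terms.

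At 4 weeks Zfp459 was the only gene called between CAC and NCAC libraries, at 3.06 ± 1.17 and 1.06 ± 0.281 TPM (SD, n = 5 each), with a log2 fold change of 0.95 ± 0.18 (SE, adjusted p = 0.0251). At an unadjusted p under 0.05 there were 2361 genes. The count of 1 was 0 by limma without CAC 4 week replicate 1 or 4 or NCAC 4 week replicate 3, 4 or 5, and 279 without CAC replicate 3, 1566 without CAC replicate 5 and 7 without NCAC replicate 1. Zfp459 also missed the threshold with lane as a term (adjusted p = 0.163), no filter on level (0.0518), the 6 marker scores (0.223), only the groups compared (0.609) and without the 3 libraries that stood apart (0.123). At 2 weeks limma called 0 genes between CAC and NCAC, with 616 at an unadjusted p under 0.05 and 0 by voom. Sord, at 20.3 ± 1.89 TPM in CAC and 26.7 ± 2.33 TPM in NCAC (SD, n = 5 each), and Cbs, at 24.7 ± 0.831 and 19.4 ± 2.08 TPM, were among the genes with the lowest p and did not pass.

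**Figure D2:**
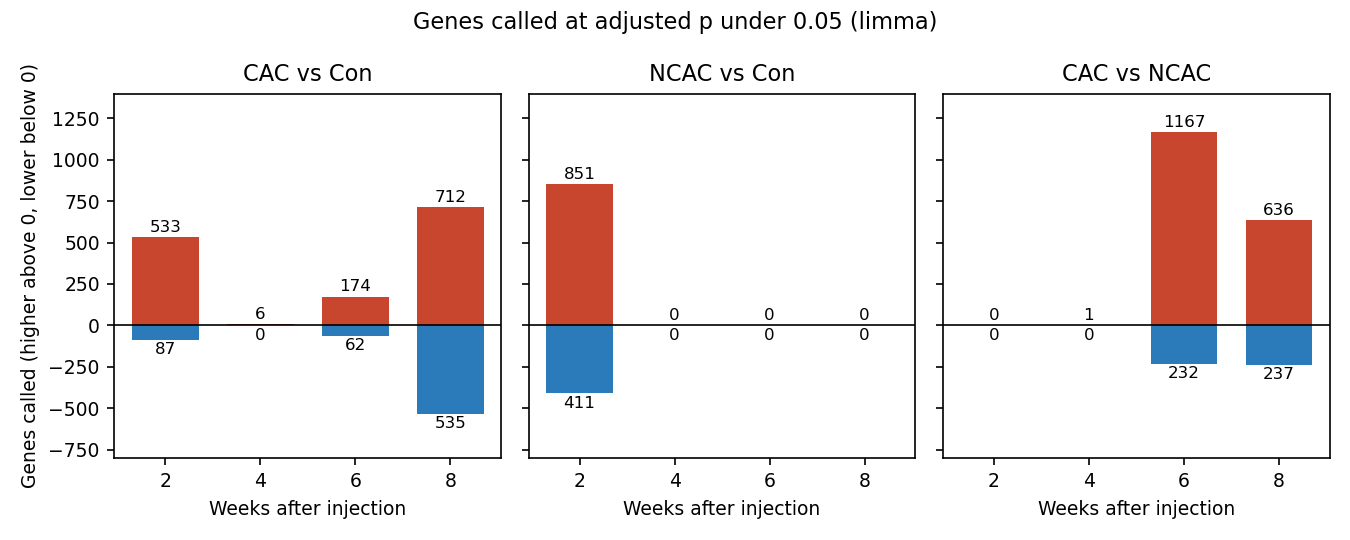
Number of genes called at an adjusted p under 0.05 (vertical axis, higher above 0 in red and lower below 0 in blue) against weeks after injection (horizontal axis) for the 3 pairs of groups. At 8 weeks 712 genes were higher and 535 lower in CAC than mock, while NCAC and mock differed in 0 genes by limma, with 636 at an unadjusted p under 0.05 and 0 by voom.

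Whether the difference between CAC and mock changed from 2 to 8 weeks was tested as an interaction, and 191 genes passed, 88 with a higher and 103 with a lower difference at 8 weeks. The difference grew by 2.08 ± 0.31 log2 units for Lcn2 (SE, adjusted p = 0.000136), by 2.74 ± 0.51 for Scgb3a1 (adjusted p = 0.00277) and by 1.68 ± 0.31 for Ch25h (adjusted p = 0.00277). It was lower by -1.95 (SE 0.35) for Ighm and by -1.18 (SE 0.22) for Tnnc1. The lists of cytokine genes (3 of 11 higher, 8 adjusted over the list alone) and reactive astrocyte genes (3 of 14 higher, 5 adjusted over the list alone) passed with an estimated correlation, with adjusted p-values of 0.0235 and 0.0357. Lcn2 and Osmr are on both lists. Of 16 glucocorticoid-responsive genes 5 were higher (12 adjusted over the list alone, adjusted p = 5.47e-17, or an adjusted p = 0.0748 with an estimated correlation). The weeks were run on different lanes, so this test carries any lane effect that differs between the groups. It also rests on the mock libraries of 2 weeks, which differed from both tumour groups of that week. The count of 191 was 76 with no filter on level, 120 with the 6 marker scores as terms and 39 with only the 4 groups compared, where Ighm had an adjusted p of 0.0589 and Scgb3a1 of 0.0696. It was 60 without CAC 2 week replicate 1, 301 without replicate 4 and 54 without replicate 5; 101, 300 and 52 without mock 2 week replicates 1, 4 and 5; 80, 104, 356 and 84 without CAC 8 week replicates 1, 2, 3 and 6; and 81, 93, 61, 100 and 293 without mock 8 week replicates 1, 2, 3, 4 and 5.

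Mock libraries of 8 and 2 weeks differed in 1710 genes, 1600 higher and 110 lower at 8 weeks. The hypothalamic peptide gene Pmch fell by 2.98 (SE 0.96), from 84.4 ± 152 TPM (SD, n = 5) at 2 weeks to 0.971 ± 0.331 TPM at 8 weeks. Mock 2 week replicate 5 was the library that stood apart in hypothalamus and pituitary markers, and the log2 difference of Pmch was -0.19 (adjusted p = 0.842) with the marker scores as terms and -1.85 (adjusted p = 0.162) without the 3 libraries that stood apart. Pmch had an adjusted p of 0.11 and 0.163 without mock 2 week replicates 2 and 5, and of 0.0534, 0.0709, 0.076 and 0.0551 without mock 8 week replicates 1, 2, 3 and 4. Ano3, a membrane protein of the anoctamin family, rose by 0.62 ± 0.12 and the protease gene Prss12 by 0.64 ± 0.12, both with an adjusted p of 0.00156. Of 13 mitochondrially encoded genes 10 fell (12 adjusted over the list alone), and the list passed with an estimated correlation (adjusted p = 0.0132). Of 18 synaptic genes 8 rose (12 adjusted over the list alone, adjusted p = 0.000512, or an adjusted p = 0.32 with an estimated correlation). These groups were on different lanes. Of the 1600 higher genes 437 were among the 533 higher in CAC than mock at 2 weeks, where independent lists would share 58.8. For NCAC it was 620 of 851, against 93.9. All groups of week 2 shared lane and age, so lane and age do not by themselves account for the shared genes. The comparisons also share the mock libraries of 2 weeks, so such overlap can arise by chance. For the other genes lane, age and a difference of those mock libraries from other groups cannot be told apart. Between mock libraries of 8 and 4 weeks, which shared a lane, limma called 0 genes, with 2059 at an unadjusted p under 0.05 and 0 by voom, and 127 with only those 10 libraries in the fit. The share of higher genes from 2 to 8 weeks was 93.6%, against 61% with TMM scaling, which called 566 genes, and 58.9% with voom, which called 550, and 593 were called with only the 10 libraries compared. The count of 1710 was 738 without mock 2 week replicate 1, 1099 without mock 2 week replicate 2, 684 without mock 8 week replicate 2 and 492 without mock 8 week replicate 3.

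The differences of CAC and NCAC from the mock libraries of 8 weeks correlated across genes with r = 0.4324, and genes are not independent replicates. Unchanged groups simulated against shared controls gave 0.5416 on average (0.4753 to 0.6084 in 100 simulations). The simulated noise was independent between genes and no simulated group had an effect, whereas CAC differed from mock in many genes. The simulated ranges are therefore only a rough reference for the correlation and the covariance. With the mock libraries split so that each difference had its own, r averaged 0.0873 over 20 splits, from -0.033 to 0.229. The covariance was 0.0117, within the simulated range of 0.0078 to 0.0131, and lay 0.0023 above the simulated mean of 0.0094.

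**Figure D3:**
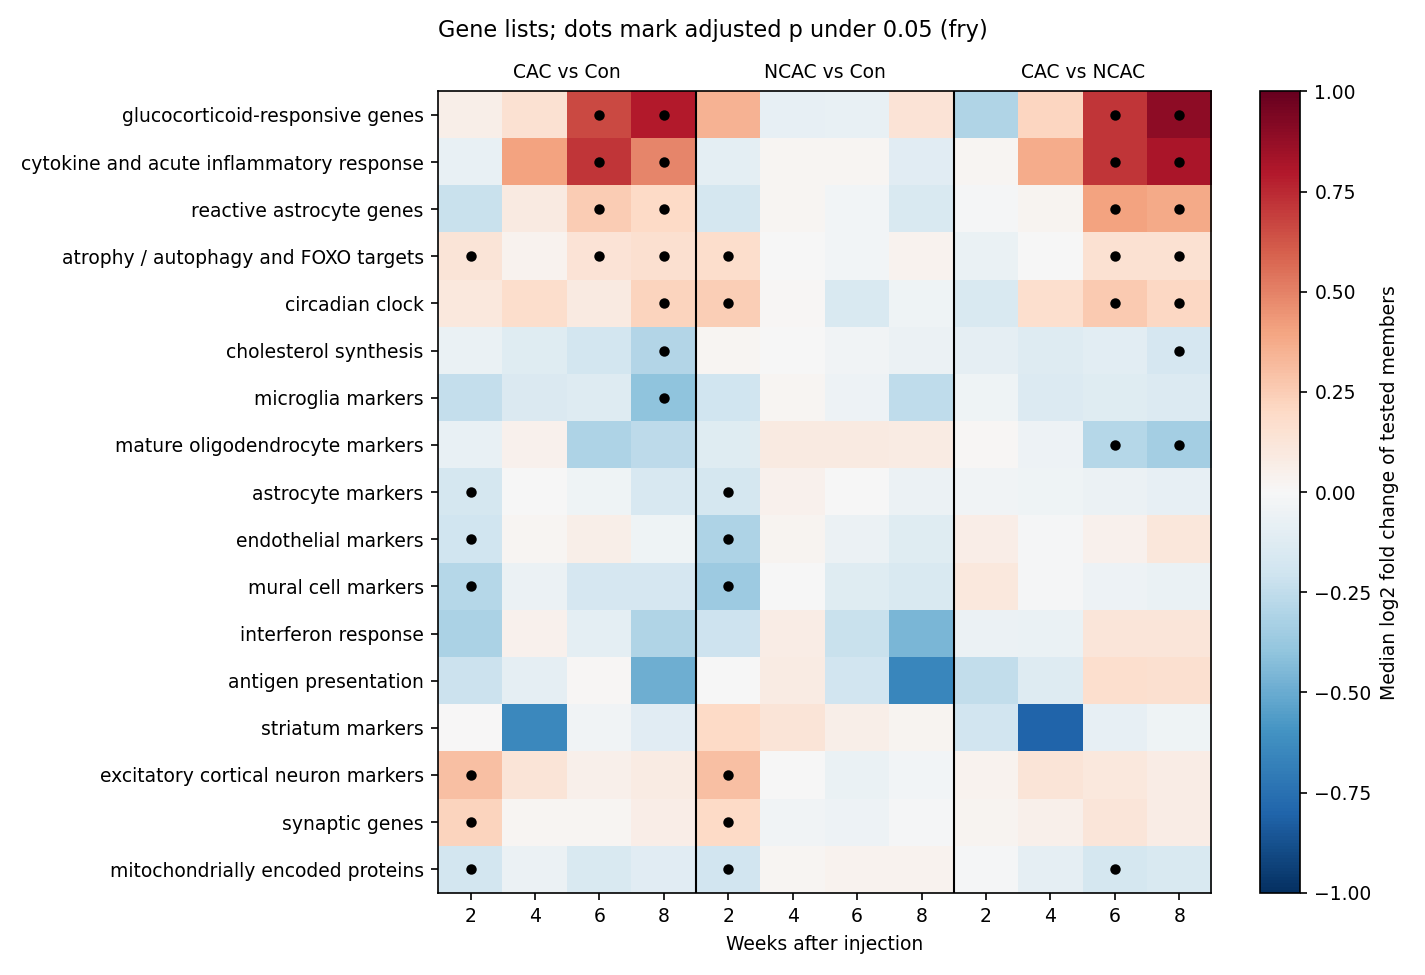
Median log2 fold change of the tested members (colour scale) for 17 gene lists (vertical axis) against weeks after injection (horizontal axis) in 3 pairs of groups, with a dot where fry gave an adjusted p under 0.05. The glucocorticoid-responsive list had a median of 0.80 and the cholesterol synthesis list one of -0.29 in CAC against mock at 8 weeks.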

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

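The tests of the 3 patterns weighed in this part were chosen after related results had been seen, while the counts over other splits of the samples were planned before their results were seen.

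The first pattern is that mock libraries of week 2 stood apart from both tumour groups, with 1262 genes called against NCAC and 620 against CAC, and 0 between CAC and NCAC by limma (616 at an unadjusted p under 0.05, 0 by voom). For NCAC, the count of 803 without mock 2 week replicate 5 stands against that library as the whole cause. The count moved more without single NCAC libraries, to 129 without replicate 2, 173 without replicate 5 and 1900 without replicate 4. Against CAC the count was 175 without mock replicate 5, which leaves an aberrant mock library open for CAC. It was 78, 79 and 1234 without CAC replicates 1, 5 and 4. Such counts therefore do not show whether mock or tumour libraries carry the pattern. With TMM scaling 2038 genes were called against NCAC. A count does not show whether the same genes were called, so the scaling of TPM stays open. Mitochondrial genes took 30.19% of TPM in mock libraries of week 2 (SD 1.97), 27.02% in NCAC (SD 2.05) and 27.07% in CAC (SD 2.73). RNA of neighbouring regions or blood cannot be told apart from a group difference, since with 6 marker scores as terms 111 genes were called, while the median effect of the 1262 genes went from 0.276 (SD 0.17) to 0.237 (SD 0.119), the median SE rose from 0.078 to 0.084 and all 1262 kept their direction. With 85.7% of the median effect left and a larger error fewer genes passed, and why the effect was smaller was not tested. An effect of the injected cells at this week stays open and untested, as does an effect of handling of the mock mice.

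The second pattern is the difference between CAC and mock at 8 weeks. With 6 marker scores as terms 1158 of the 1247 calls were kept in the same direction. This argues against RNA of the scored regions or blood as the whole cause. The scores do not cover white matter or hippocampus, so RNA of those regions stays open. With TMM scaling 1104 calls were kept, which argues against the scaling of TPM. A candidate explanation that remains is a response of the neocortex to the cachectic tumour, as a hypothesis found and tested on the same data. A change in the share of cell types was not tested.

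The third pattern is that CAC 8 week replicate 3 showed a weak response in many genes, with Fkbp5 lowest of its group at 17.7 TPM, although Lcn2 was highest there, at 13.2 TPM. Haemoglobin RNA took 2.24% of its TPM, against at most 0.239% in the other 6 libraries, and diluted other genes by 0.0311 log2 units, or 13.3% of the median shortfall of 0.233 over the 712 risen genes. Dilution of that size leaves most of the median shortfall open, and other effects of blood on the library were not tested. A swap with a mock or NCAC library of 8 weeks would leave a partner among them, and 0 of those libraries scored above the lowest other CAC library in the genes called at 6 weeks, though NCAC replicate 3 (0.253) scored above this library (0.147). A milder course of cachexia in this mouse stays open and was not tested.

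In some comparisons fewer than 5 of the 100 splits, counting the real one, called as many genes as the real split. Among these were CAC against mock at 2 weeks (real 620, highest other 935, 3 of 100), 6 weeks (236, 235, 1 of 100) and 8 weeks (1247, 2259, 2 of 100). The others were NCAC against mock at 2 weeks (1262, 1229, 1 of 100), the change from 2 to 8 weeks (191, 857, 3 of 100) and mock at 8 against 2 weeks (1710, 662, 1 of 100). These shares were not adjusted over the 16 comparisons, and some arbitrary splits called more genes than the real one, so chance is not excluded. The share was 5 of 100 or more for CAC against NCAC at 6 weeks (1399, 3727, 5 of 100), 8 weeks (873, 2022, 5 of 100) and 4 weeks (1, 1493, 10 of 100). It was also above that for CAC against mock at 4 weeks (6, 1106, 11 of 100). Splits that call several times the real count, as at 4 weeks, for CAC against NCAC and for the changes from 2 and from 6 to 8 weeks, point to a structure of the samples, whose source was not tested. Where the real count was 0, all 100 splits were as large, with a highest other of 3, 2 and 0 for NCAC against mock at 4, 6 and 8 weeks, 120 for CAC against NCAC at 2 weeks, 645 for the change from 6 to 8 weeks and 0 for mock at 8 against 4 weeks. These 0 counts are limma's, with voom also at 0, and 89, 953, 636, 616, 186 and 2059 genes at an unadjusted p under 0.05.

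For counts of lists passing camera, chance could be excluded for CAC against mock at 2 weeks (real 22, highest other 23, 3 of the 100 splits) and NCAC against mock at 2 weeks (23, 24, 2 of 100). The median of the other splits was 8 to 15 lists over the 14 comparisons, so the preset correlation passes lists on arbitrary splits as well. Chance could also not be excluded for CAC against mock at 4, 6 and 8 weeks (13, 16 and 16, with 20, 20 and 22 at most, 39, 13 and 24 of 100). Nor could it for NCAC against mock at 4, 6 and 8 weeks (13, 9 and 14, with 17, 14 and 22 at most, 24, 37 and 34 of 100) or for CAC against NCAC at 2, 4, 6 and 8 weeks (11, 17, 18 and 17, with 23, 23, 22 and 21 at most, 67, 8, 12 and 18 of 100). The changes from 2 to 8 and from 6 to 8 weeks (14 and 12, with 26 and 22 at most, 60 and 67 of 100) were likewise not set apart from chance.

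Single libraries far from the rest of their group were found in 30 of 273 pairs of gene and group. Chance marks about 1 in 20 groups, or about 14 here, but that rate does not hold for genes at or near 0 in most libraries, such as Prl, Mlana and Tyr, so the number found is no evidence of an excess. Values are the gap to the nearest library as a share of the range. In CAC 8 week replicate 3 Lcn2 was highest, at 13.2 TPM (0.587), and Lrg1 lowest, at 5.12 TPM (0.599). Mock 8 week replicate 5 was highest for Lrg1 (0.813) and Ighm (0.884) and lowest for Opalin (0.763). Hmgcs1 was lowest in CAC 4 week replicate 2 (0.71), Fabp7 highest in mock 2 week replicate 3 (0.821) and Gkn3 lowest in CAC 2 week replicate 3 (0.716). The choroid plexus gene Ttr was lowest in mock 4 week replicate 4 (0.803), NCAC 6 week replicate 3 (0.797) and NCAC 8 week replicate 5 (0.803). The thalamus marker Prkcd was highest in mock 2 week replicate 5 (0.896), CAC 4 week replicate 4 (0.8) and NCAC 4 week replicate 1 (0.756), and the olfactory marker Omp in CAC 8 week replicate 5 (0.598). The pituitary gene Prl was highest in mock 2 week replicate 5 (1770 TPM, 0.857), NCAC 4 week replicate 4 (0.89), CAC 6 week replicate 3 (1), NCAC 6 week replicate 5 (0.942), CAC 8 week replicate 1 (1), NCAC 8 week replicate 2 (0.91) and mock 8 week replicate 2 (1). Xist was highest in CAC 2 week replicate 2 (0.887) and lowest in NCAC 8 week replicate 4 (0.781). Of pigment cell genes, Pmel was highest in mock 8 week replicate 3 (0.832), Mlana lowest in mock 6 week replicate 4 (0.92) and highest in NCAC 8 week replicate 5 (1), Tyr highest in mock 6 week replicate 3 (0.8) and NCAC 8 week replicate 2 (0.761), and Dct highest in mock 2 week replicate 3 (0.795).

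The difference between CAC and mock itself differed between 8 and 2 weeks in 191 genes by the test of that difference. In log2 units the largest positive changes were in Etnppl (2.79), Scgb3a1 (2.74), Lcn2 (2.08), Rtp1 (2.07), Agt (1.99), Tmem252 (1.91), Sult1a1 (1.81), Lrg1 (1.78), Ch25h (1.68) and Phyhd1 (1.62). The largest negative changes were in Ighm (-1.95), Gkn3 (-1.68), Myl4 (-1.23), Opalin (-1.20), Tnnc1 (-1.18), Hkdc1 (-1.06), Ninj2 (-0.92), Apln (-0.92), Pak7 (-0.89) and Hs3st2 (-0.89). Part of such a change can lie in the 2 week groups. The log2 difference of Agt was -1.055 in mock at 8 against 2 weeks, and that of Pak7 was 0.577 in CAC against mock at 2 weeks. Gkn3 missed the threshold in 17 of 30 alternatives, Sult1a1 in 15, Opalin and Apln in 13 each, Agt in 6, Hkdc1 and Myl4 in 5 each, Hs3st2, Scgb3a1 and Lrg1 in 2 each and Etnppl and Ighm in 1 each.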

How the results depend on the processing

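Of the alternatives, voom on estimated reads, the 6 marker scores as terms, the fit without the 3 libraries that stood apart, and fry were chosen after the data were seen, as were, for the list tests, the replicate block and leaving out each library. Counts stayed within 1.5 times with a pseudocount of 0.1 and with robust moderation in every gene comparison.

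With no filter on level, the number of called genes was 2 for CAC against mock at 4 weeks, 780 and 1 for NCAC against mock at 2 and 6 weeks, 0 and 904 for CAC against NCAC at 4 and 6 weeks and 76 for the change from 2 to 8 weeks. With TMM scaling it was 1 for CAC against mock at 4 weeks, 2038 for NCAC against mock at 2 weeks, 719 for CAC against NCAC at 6 weeks and 566 for mock at 8 against 2 weeks. With voom it was 2 for CAC against mock at 4 weeks, 861 for CAC against NCAC at 6 weeks and 550 for mock at 8 against 2 weeks. With the 6 marker scores it was 3 and 1 for CAC against mock at 2 and 4 weeks, 111 for NCAC against mock at 2 weeks, 0 and 304 for CAC against NCAC at 4 and 6 weeks and 120 for the change from 2 to 8 weeks. With only the groups compared, where fewer samples estimate the spread, it was 0 and 0 for CAC against mock at 2 and 4 weeks, 7 for NCAC against mock at 2 weeks, 0, 628 and 284 for CAC against NCAC at 4, 6 and 8 weeks, 39 for the change from 2 to 8 weeks, and 593 and 127 for mock at 8 against 2 and 4 weeks. Without the 3 libraries that stood apart it was 349, 2 and 2021 for CAC against mock at 2, 4 and 8 weeks and 0 and 1974 for CAC against NCAC at 4 and 8 weeks. With lane as a term at 4 weeks it was 0 for CAC against mock, 2 for NCAC against mock and 0 for CAC against NCAC. Apart from the fits of fewer groups, the cause was not tested.

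With the replicate number as a block the count was 1 and 490 for CAC against mock at 4 and 8 weeks and 0 and 257 for CAC against NCAC at 4 and 8 weeks, and it stayed within 1.5 times in the other comparisons of arms within a week. It was not fitted for the changes between weeks or between mock groups. The numbers do not pair the mice: correlations of libraries with the same number ran from -0.25 to 0.28, 4, 6, 5 and 4 of 15 pairs per week exceeded 0.1, and 0, 1, 1 and 1 of 15 libraries correlated best with their own number. The cause was not tested.

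For list tests, an estimated correlation gave 0, 0, 2 and 0 lists for CAC against mock at 2, 4, 6 and 8 weeks, 0 in each week for NCAC against mock, 0, 0, 0 and 1 for CAC against NCAC, and 2 and 0 for the changes from 2 and from 6 to 8 weeks. Fry, which asks another question, gave 8, 0, 7 and 8, then 8, 0, 0 and 0, then 0, 0, 9 and 8, then 3 and 0 in the same order. TMM scaling gave 4 lists for NCAC against mock at 6 weeks, where the preset correlation gave 9. The correlation of the CAC and NCAC differences at 8 weeks was 0.087 with split controls, where each difference also rests on fewer mock libraries, and the cause was not tested.

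Leaving out each library in turn gave, as lowest and highest counts of genes, 78 and 1234, 1 and 760, 54 and 407, and 721 and 1763 for CAC against mock at 2, 4, 6 and 8 weeks. They were 129 and 1900 for NCAC against mock at 2 weeks and, by limma, 0 in every case at 4, 6 and 8 weeks (89, 953 and 636 at an unadjusted p under 0.05 with all libraries). For CAC against NCAC they were 0 and 0, 0 and 1566, 342 and 2508, and 407 and 1640. They were 52 and 356 for the change from 2 to 8 weeks, 0 and 0 for that from 6 to 8 weeks, and 492 and 2039, and 0 and 0, for mock at 8 against 2 and 4 weeks. The cause was not tested. For lists they were 17 and 24, 8 and 17, 13 and 18, and 12 and 19 for CAC against mock, 18 and 24, 6 and 16, 4 and 11, and 9 and 16 for NCAC against mock, 10 and 17, 11 and 19, 14 and 18, and 15 and 19 for CAC against NCAC, and 13 and 18, and 10 and 15 for the changes. The correlation of differences at 8 weeks ran from 0.32 to 0.505.

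Of 343 results for named genes 337 kept direction and side of the threshold with a pseudocount of 0.1, 292 with no filter, 314 with TMM scaling, 338 with robust moderation, 255 with marker scores and 235 with only the groups compared. The numbers were 302 of 341 with voom and 3346 of 3884 when single libraries were left out. No called gene changed direction in these. Of genes not called, with lane as a term at 4 weeks the log2 difference of CAC from mock changed sign for Btg2 (-0.14), Lcn2 (-0.11), Hif3a (-0.60), Sult1a1 (-0.058), Arrdc2 (-0.16), Zbtb16 (-0.12) and Npas4 (-0.22), and Jun at 6 weeks ranged from -0.014 without CAC replicate 3 to 0.233 without CAC replicate 4. The cause was not tested. At the depth of these libraries a gene of 1 TPM rests on 28.1 reads for 2000 exon bases, which limits the precision of low levels such as those of Lcn2 in mock libraries.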

Other observations

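All tests of hypotheses in this part were chosen after related results had been seen.

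Of 14 neuropeptide and neurotrophin genes 3 were lower in CAC than mock at 8 weeks (4 adjusted over the list alone), and the list had an adjusted p = 0.0162 by camera, or an adjusted p = 0.409 with an estimated correlation. Of 15 genes of fasting, ketone and fatty acid use 2 were higher and 5 lower (2 and 6 adjusted over the list alone), with a median of -0.09 and a mean of 0.03, and the list did not pass (adjusted p = 0.113). Of 16 endothelial markers 2 were higher and 4 lower (6 and 6 adjusted over the list alone), and the lists of heat shock and of the unfolded protein response had 0 of 13 and 1 of 17 members higher and 0 lower by limma. Melanoma cells can express pigment cell genes. The highest Pmel level was 1.53 TPM in mock, 1.59 TPM in CAC and 1.62 TPM in NCAC libraries, the highest Dct level 1.62, 0.998 and 0.757 TPM, and the highest Tyr level 0.0622, 0.115 and 0.105 TPM, with no test of these differences.

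A hypothesis was that the late response begins before 8 weeks. The 39 genes called at 8 weeks with a fold above 2 (30 higher and 9 lower in CAC) were scored in the libraries of earlier weeks, whose levels do not enter the fold change at 8 weeks but do enter the estimate of spread in the fit that called the genes, with exact two-sided permutation tests over 252 splits and adjustment over 6 tests. In CAC at 6 weeks the score was 1.173 ± 0.285 (SD, n = 5) above mock, with 5 of 5 libraries above every mock library, an exact p of 0.00794, which is the smallest these splits can give, and an adjusted p of 0.0476, in line with the hypothesis. In CAC at 4 weeks the score was 0.464 ± 0.605 with 2 of 5 libraries above every mock library (adjusted exact p = 0.477), and at 2 weeks the adjusted exact p was 0.825. In NCAC the adjusted exact p was 0.572, 0.825 and 0.825 at 2, 4 and 6 weeks. A p that misses the threshold does not show that earlier weeks were without a response, and the difference between weeks in this score was not tested.

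Another hypothesis was that the glucocorticoid-responsive list moves with other lists from mouse to mouse among the 7 CAC libraries of 8 weeks, tested for 3 lists with exact permutation over 5040 orders. The list means of glucocorticoid and microglia genes were inversely related (Pearson r = -0.845, exact p = 0.00476, adjusted p = 0.0143, and Spearman rho = -0.964, exact p = 0.00278, adjusted p = 0.00834). Without replicates 3 and 1, which lay farthest from the median, r was -0.849. Glucocorticoid levels were not measured, and neither a shared severity of the response nor the share of microglia among cells was tested as a source of this relation. Cholesterol synthesis gave r = -0.561 (exact p = 0.168, adjusted p = 0.252; rho = -0.429, exact p = 0.354), and r was -0.026 without replicates 3 and 1, so the relation rests on those libraries. The cytokine list gave r = -0.112 (exact p = 0.849, adjusted p = 0.849; rho = -0.429, exact p = 0.354) and -0.165 without them.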
